A study of Mus musculus with 3 samples.

How the data were processed

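The data were 3 polyA-selected RNA-seq libraries, prepared with Illumina TruSeq from pro-B cells sorted out of mouse bone marrow, per the labels. The sort gate was B220 positive, CD19 positive, IgM negative, CD24 positive and either BP1 positive or negative. The sample titles name it Hardy fraction BC, read here as fractions B, C and C′ together. The markers listed here do not by themselves exclude later IgM negative pre-B cells. The libraries came from a wild-type mouse line on the C57BL/6 background and from lines with Ikaros zinc finger 1 or zinc finger 4 mutated on both alleles, here called the ZnF1 mutant and the ZnF4 mutant. Each genotype had 1 library, and the sources used here do not say how many animals each sort pooled.

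The deposited values are RPKM, per the file headers, with a transcript length beside each RefSeq transcript. TopHat and bedtools are named in the submitters' processing notes, with mm9 as the genome build; their versions, the read length, the counting rule and what the normalising read total included are not given in the sources used here. All deposited RPKM values were multiples of 0.1, so each is known to within 0.05 RPKM. Whole reads could not be recovered from values rounded in this way, so the depth of each library is unknown, and no counting interval is given.

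The table held 26531 transcripts with values and 1 row without values, which was left out. These rows carried 22098 gene symbols, and 3305 symbols had more than 1 row. For each symbol the transcript with the highest mean over the 3 libraries was used. Summed over all rows, RPKM multiplied by transcript length came to 87.3% of the normalising read total in wild type, 87.7% in ZnF1 and 81.7% in ZnF4. Rows of 1 symbol may share reads and the counting rule is not given, so these sums are not shares of reads. Several genes that every cell uses and that have near-identical genomic copies were listed close to 0, so a value of 0 is reported here as listed at 0 and no fold of a single gene against it is given. Such genes enter list medians and counts with the pseudocount, and a median that rests on such a gene is marked. Genes with close copies (globins, Bcl2a1 genes, Vpreb genes, ribosomal proteins) have uncertain levels.

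Ratios between libraries were computed as differences of log2(RPKM + 0.5), which understates the differences of low genes, from the RPKM as deposited. The 10418 genes with a mean of at least 1 RPKM over the 3 libraries entered the counts. Because a group of 1 library leaves no spread to test against, no p-value was computed between genotypes. A size rule took the place of a test, and a gene was called apart when the libraries differed by at least 2-fold on this scale. The comparisons were ZnF1 mutant against wild type, ZnF4 mutant against wild type, and ZnF4 mutant against ZnF1 mutant.

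Before the data were examined, 27 gene lists were fixed: Ikaros family and partner complexes, pre-B receptor signalling, V(D)J recombination, B-lineage transcription factors, integrins and adhesion, cytokine and stromal receptor signalling, DNA replication, mitosis, cell cycle regulators, interferon response, immediate early and stress genes, apoptosis, Notch pathway, glycolysis and glucose uptake, ribosomal proteins, oxidative phosphorylation, sex-linked genes, chromosome 11 neighbours of Ikzf1, and markers of late pre-B and immature B cells, progenitors, T cells, granulocytes and monocytes, erythroid cells, megakaryocytes, NK and dendritic cells, plasma cells and bone marrow stroma. For each list with at least 3 measured members the median log2 ratio was ranked as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The 95% interval of a list median was taken from the ordered members by the binomial distribution, as if the members were independent. These percentiles describe the libraries at hand and are not tests across animals. Older and newer symbols of a gene were counted as 1 gene. Syk and Ahsp matched no symbol in the table and were not analysed here.

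The named genes were chosen by a rule fixed at the same time. Ikzf1 came before all others. For each comparison the rule took the 12 highest and 12 lowest log2 ratios among genes with at least 5 RPKM in the higher library of the pair. It also took up to 4 members of each list with the largest log2 ratios in either direction; clone and gene model names were to be counted but not described. Genes named outside this rule, apart from the markers a test names, are marked as chosen after their values were seen.

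The comparisons with wild type share its single library, so chance in that library moves both. In 100 simulations of unchanged libraries, noise for each library was drawn from the ZnF1 to wild-type log2 ratios within each expression bin, with random sign. This noise contains any real ZnF1 differences and is therefore generous. The overlap of independent lists (the product of the list sizes divided by the genes tested) is given beside it. The wild-type library could not be split.

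The size rule and the list percentile were tested on simulated data. With 200 genes altered 3-fold per mutant, rounding as in the table and noise of 0.2 on the log2 scale, 95.9% of the altered genes tested were called for the ZnF1 comparison and 94.8% for the ZnF4 comparison, with 5 and 6 unaltered genes called among 10229. This noise was a chosen value, the same at every expression level. The noise between the real libraries is unknown with 1 library per genotype, so these figures are not error rates for these data. Of 200 random lists of 20 genes drawn from the 10418 genes of the ZnF4 comparison, 1.0% ranked above and 2.0% below the central 95% of matched random lists.

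The alternatives tried were pseudocounts of 0.1 and 1 RPKM, scaling by the median of ratios, to the same sum of RPKM, or to the same sum without the 20 most abundant genes, the sum of a symbol's rows, no expression filter or a mean of at least 5 RPKM, and size rules of 1.5-fold and 4-fold. Chosen after seeing the data were the removal of transcripts shorter than 200 nt, the subtraction of the median log2 ratio within 20 bins of transcript length, and the removal of genes listed at 0 in any library. The genome at hand was GRCm38, another build than the deposited values used, so no coordinates are given; its transcripts served only to search ribosomal protein transcripts for stretches shared with pseudogenes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.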

Results

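Ikaros, encoded by Ikzf1, is a transcription factor that lymphocyte precursors require, and it contacts DNA through a cluster of zinc fingers. RNA was sequenced from sorted bone marrow pro-B cells of wild-type mice and of mice mutant for Ikaros zinc finger 1 or zinc finger 4, to ask how the loss of each finger alters gene expression at this stage of B-cell development. Each genotype was represented by 1 library, so no difference reported here has a replicate check, and all differences are between libraries. The RPKM values summed to 309932 in the wild-type library, 308705 in the ZnF1 library and 276146 in the ZnF4 library. The read depth of each library is unknown. At least 1 RPKM was listed for 10428 genes in wild type, 10340 in the ZnF1 mutant and 10285 in the ZnF4 mutant.

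Ikzf1 itself (NM_001025597) was listed at 232.6 RPKM in wild type, 237.5 RPKM in the ZnF1 mutant and 496.6 RPKM in the ZnF4 mutant. This value covers the whole transcript and therefore does not test the loss of the sequence for a single finger. The related factor Ikzf3 (Aiolos) was lower in the ZnF1 mutant and higher in the ZnF4 mutant, at 58.1 RPKM in wild type, 20.4 RPKM in ZnF1 and 263.3 RPKM in ZnF4. Among the 20 measured genes of the Ikaros family and partner complexes, Ikzf3 was the only member at least 2-fold from wild type in the ZnF1 mutant. In the ZnF4 mutant, Ikzf1 and Ikzf3 were at least 2-fold higher, and the chromatin remodelling subunits Mta3 (30.1 RPKM in wild type, 9 RPKM in ZnF4) and Mta1 (65.7 and 30.3 RPKM) were at least 2-fold lower.

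The genes of the sort gate were expressed in all 3 libraries; these genes were chosen after their values were seen. Cd19 was listed at 350.2 RPKM in wild type, 423.2 RPKM in ZnF1 and 568.4 RPKM in ZnF4, and Ptprc, which encodes the B220 antigen, at 71.6, 74.4 and 92.8 RPKM in the same order. Cd24a was listed at 213.1, 108.3 and 247.3 RPKM, and Enpep, which encodes BP1, at 24.2, 18.6 and 12.9 RPKM. Among the sex-linked genes, Xist was listed at 70.3 RPKM in wild type, 55.6 RPKM in ZnF1 and 85.1 RPKM in ZnF4, while Ddx3y, Eif2s3y, Uty and Kdm5d, on the Y chromosome, were listed at 0 in all 3 libraries.

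In the ZnF1 mutant, interferon response genes and several genes of early progenitors were higher than in wild type, and most granulocyte and several erythroid and T-cell marker genes were lower. In total 191 genes were at least 2-fold higher and 226 at least 2-fold lower than in wild type, out of 10418. The median log2 ratio of all genes was -0.04.

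All 26 measured interferon response genes had higher values in the ZnF1 mutant than in wild type, 14 of them by at least 2-fold, and the list's median log2 ratio was 1.10, at percentile 100 among random lists. Ifi44 was listed at 15.1 RPKM in ZnF1 against 2.1 RPKM in wild type, and Oas2, an antiviral oligoadenylate synthetase, at 8.6 against 1.5 RPKM. Usp18, which removes the ubiquitin-like protein Isg15 from its targets, was listed at 18.6 against 4.1 RPKM, and Ifit1 at 3.6 against 0.6 RPKM. Bone marrow granulocyte markers differed between the same libraries in the opposite direction, with a median log2 ratio of -1.22.

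Of 11 measured progenitor markers, 4 were at least 2-fold higher in ZnF1 and 1 was at least 2-fold lower, with a median log2 ratio of 0.52 at percentile 100. Those higher were Flt3, a cytokine receptor of early lymphoid progenitors (15.2 RPKM in ZnF1 against 2.9 RPKM in wild type), Ly6a, which encodes Sca-1 (15.2 against 4.9 RPKM), and the homeobox genes Meis1 (9 against 3 RPKM) and Hoxa9 (2.8 against 0.6 RPKM). Gfi1b, a transcriptional repressor that acts within the erythroid and megakaryocyte lineages, was lower (1.4 against 7.9 RPKM). Without the expression filter the progenitor median was 0.22.

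Genes of V(D)J recombination were listed mostly within 2-fold of wild type, with 1 of 15 higher and 1 lower. Rag1, which encodes a subunit of the recombinase, was listed at 427.6 RPKM in ZnF1 against 203.2 RPKM in wild type, and Polm, a DNA polymerase of end joining, at 12 against 30.1 RPKM. Of the 21 measured genes of pre-B receptor signalling, Bank1 was at least 2-fold higher in ZnF1 (18 against 4.6 RPKM), and Zap70 (1.6 against 6.5 RPKM) and the inhibitory receptor Cd22 (14.9 against 42.4 RPKM) were at least 2-fold lower. The median of this list was 0.24. None of the 26 B-lineage transcription factors was 2-fold apart, the highest being Erg (175.8 against 95.9 RPKM) and Bcl11a (31.1 against 18.6 RPKM). Among 23 late pre-B and immature B markers, 4 were at least 2-fold higher and 1 lower, with a median of 0.21, or 0.13 at a mean of at least 5 RPKM. The antigen presentation gene Cd74 (212.4 against 78.5 RPKM), the costimulatory receptor Cd40 (10.3 against 3.5 RPKM) and Ms4a1, which encodes CD20 (10.9 against 4.1 RPKM), were among those higher, and the BAFF family receptor Tnfrsf13b was lower (4.7 against 12.2 RPKM).

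All 19 measured granulocyte and monocyte markers were lower in ZnF1 than in wild type, 13 of them by at least 2-fold, at percentile 0. Elane, the neutrophil elastase gene, was listed at 1.2 RPKM in ZnF1 against 7.6 RPKM in wild type, and the granule protein gene Camp at 18 against 59.6 RPKM. Of 7 erythroid markers 4 were at least 2-fold lower, with a median of -1.13 at percentile 0, including Car2 (14.4 against 49 RPKM) and the heme synthesis gene Alas2 (1.7 against 4.3 RPKM). Hbb-b1 and Hbb-b2, a pair of near-identical beta globin genes whose reads may be shared, were listed at 12 and 12.3 RPKM in ZnF1 against 27.7 and 28.5 RPKM in wild type. Of 8 measured T-cell markers 4 were at least 2-fold lower and 1 higher, with a median of -1.03 at percentile 0. The adaptor Lat (1.3 against 13.3 RPKM), Thy1 (0.7 against 7 RPKM) and Ubash3a (6.3 against 27.8 RPKM) were lower, and Cd27, also found on lymphoid progenitors, was higher (15.6 against 5.4 RPKM). Without the expression filter the medians were -0.35 for the erythroid and -0.12 for the T-cell markers. The 95% interval of the median over the members spanned 0 for the erythroid (-1.73 to 0.26), T-cell (-2.94 to 1.45), progenitor (-0.15 to 1.58), pre-B receptor (-0.33 to 0.52) and late pre-B lists (-0.18 to 0.71).

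DNA replication genes were slightly lower in ZnF1, with a median log2 ratio of -0.28 at percentile 0.01 and no member of 26 reaching 2-fold. The replication licensing factor Cdt1 was listed at 28.2 RPKM against 55.2 RPKM in wild type. The 25 mitosis genes had a median of -0.24, also with no member 2-fold apart. Among cell cycle regulators, Myc (22.3 against 51.9 RPKM) and cyclin D2, Ccnd2 (18.9 against 40.8 RPKM), were at least 2-fold lower, and Cdkn1a, which encodes the inhibitor p21, was at least 2-fold higher (54.7 against 25.7 RPKM).

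Among genes with at least 5 RPKM in the higher library, the 12 highest log2 ratios in the ZnF1 mutant all belonged to named genes. The largest was that of Muc13 (NM_010739), a cell surface mucin, listed at 23 RPKM in ZnF1 and 1.4 RPKM in wild type, a log2 ratio of 3.63. Nebl was listed at 6.5 against 0.3 RPKM, the scavenger receptor Cd36 at 47 against 6 RPKM, and Kdr, a receptor for vascular endothelial growth factor, at 7.3 against 0.6 RPKM. The immune-associated GTPase genes Gimap4 (159.6 against 28.1 RPKM) and Gimap3 (21.3 against 3.6 RPKM) followed, with the endosomal RNA sensor Tlr7 (8.1 against 1.2 RPKM), Prss12 (6.8 against 0.9 RPKM), Fxyd6 (98.4 against 19.2 RPKM) and Fgd2 (34.6 against 6.9 RPKM). The microRNA gene Mir147, a feature of 80 nt, was listed at 10.1 against 1.5 RPKM. At the other end, the kinase gene Camk2b (NM_001174053) was listed at 14.6 RPKM in wild type and at 0 in ZnF1, and the peptide transporter Slc15a2 at 7.1 RPKM and at 0. Emid1 (1.8 against 25.1 RPKM), Nrgn (6.2 against 69.4 RPKM), the metallothionein gene Mt1 (1.8 against 16.9 RPKM), Rbpms (1.4 against 13.4 RPKM), the lipid phosphatase gene Inppl1 (1.2 against 10.8 RPKM), Prg3 (0.4 against 5.4 RPKM), the myosin light chain gene Myl4 (44 against 282 RPKM) and Khdrbs3 (0.5 against 5.5 RPKM) were lower in ZnF1.

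In the ZnF4 mutant, Dntt and 6 of 11 progenitor markers were at least 2-fold lower than in wild type, 11 of 23 late pre-B and immature B markers were at least 2-fold higher, and the medians of glycolysis, DNA replication and mitosis genes were lower, with 6 of 18, 1 of 26 and 0 of 25 members at least 2-fold lower. In total 387 genes were at least 2-fold higher and 737 at least 2-fold lower. The median log2 ratio of all genes was -0.14 and scaling by the median of ratios shifted it by 0.13, so list medians below are followed by their distance from this value. Of the genes 2-fold apart, 34.4% were higher in the deposited values, against 46.5% after median-of-ratios scaling, 49.1% after scaling to the same sum and 48.9% after scaling to the same sum without the 20 most abundant genes.

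Dntt, which encodes the terminal transferase that adds nucleotides at V(D)J joints, was listed at 20 RPKM in ZnF4 against 562.7 RPKM in wild type (NM_001043228), a log2 ratio of -4.78. Of the 15 recombination genes, Rag2 (21.3 against 56.4 RPKM) and Poll (6.1 against 15.6 RPKM) were also at least 2-fold lower, and Polm, the polymerase most similar to terminal transferase, was higher (130.7 against 30.1 RPKM). The median of this list was -0.11, 0.03 from the all-gene median, at percentile 64.6. It turned positive under each of the 3 other scalings, and was -0.36 at a mean of at least 5 RPKM and -0.24 with the length trend subtracted.

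Of 11 measured progenitor markers, 6 were at least 2-fold lower in ZnF4 and none was 2-fold higher, with a median of -1.14, -1.0 from the all-gene median, at percentile 0. This median is the value of Hoxa9, listed at 0.6 RPKM in wild type and at 0 in ZnF4, so the pseudocount sets it; over the 9 markers listed above 0 in all libraries, a choice made after seeing the data, it was -0.79. Egfl7 was listed at 2.5 RPKM in ZnF4 against 47.3 RPKM in wild type, Meis1 at 0.2 against 3 RPKM, Ly6a at 0.6 against 4.9 RPKM and Flt3 at 0.3 against 2.9 RPKM, while Hoxa7 was listed at 0 in ZnF4 and at 2 RPKM in wild type. The progenitor median was -2.81 with a pseudocount of 0.1 RPKM, -0.68 at a mean of at least 5 RPKM and -0.35 without the expression filter. Of 23 late pre-B and immature B markers, 11 were at least 2-fold higher and 1 at least 2-fold lower. The median was 0.95, 1.08 from the all-gene median, at percentile 100. By any amount, 18 members were above wild type and 5 below. Those below included Il2ra (9.8 against 19.7 RPKM) and Spn (67 against 86.2 RPKM), both chosen after their values were seen. Spn encodes CD43, also a marker of earlier pro-B cells, so its place in this list is doubtful. Cd74 was listed at 462.4 against 78.5 RPKM, Cd40 at 41.2 against 3.5 RPKM, Ms4a1 at 25 against 4.1 RPKM and the class II gene H2-Aa at 125.9 against 29.3 RPKM. Cxcr5, a chemokine receptor of follicular B cells, was lower (0.8 against 8.2 RPKM).

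Among B-lineage transcription factors, Erg was listed at 4.7 RPKM in ZnF4 against 95.9 RPKM in wild type, Id3 at 22.4 against 74.8 RPKM and Lef1 at 52.8 against 154.9 RPKM, while Bach2 was higher (233.4 against 97.2 RPKM). Of the 26 factors 2 were at least 2-fold higher and 3 lower, and the median was 0.12, 0.25 from the all-gene median, while the mean was -0.11. In pre-B receptor signalling 3 of 21 genes were at least 2-fold higher, namely Cd72 (706.9 against 198.3 RPKM), Cd22 (103.7 against 42.4 RPKM) and the kinase Lyn (114.8 against 56.4 RPKM), and the adaptor Lcp2 was lower (3 against 6.9 RPKM). The median of this list was 0.34, 0.48 from the all-gene median.

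Of 18 glycolysis and glucose uptake genes 6 were at least 2-fold lower in ZnF4 and none at least 2-fold higher, with a median of -0.77, -0.64 from the all-gene median, at percentile 0. As fixed, this list also held Txnip, Nr3c1 and Cnr2, which encode neither glycolytic enzymes nor glucose transporters. Ldha was listed at 19.5 against 81.2 RPKM, Pkm2 at 17.2 against 46.7 RPKM, Tpi1 at 12.6 against 32.6 RPKM and Pgk1 at 3.3 against 7.5 RPKM. DNA replication genes had a median of -0.69, -0.55 from the all-gene median, at percentile 0, and 1 of 26 members, Ccne1, was at least 2-fold lower (13.6 against 30.8 RPKM). The median of the 25 mitosis genes was -0.56, -0.42 from the all-gene median, with no member 2-fold apart. Among cell cycle regulators, Cdkn1a (5.3 against 25.7 RPKM), Myc (12.5 against 51.9 RPKM) and Ccnd3 (116.8 against 265 RPKM) were lower, and Cdkn1c was higher (3.3 against 1 RPKM).

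Integrin and adhesion genes included 9 of 27 members at least 2-fold lower and 3 higher in ZnF4, with a median of -0.52, -0.39 from the all-gene median, at percentile 0.14. L-selectin, Sell, was listed at 11 against 63.9 RPKM, Itgal, an integrin chain of leukocytes, at 6 against 22.4 RPKM and Zyx at 4.9 against 20.5 RPKM, while the catenin gene Ctnnd1 was higher (26.8 against 4.7 RPKM). In the Notch pathway 5 of 16 members were at least 2-fold lower and none at least 2-fold higher, with a median of -0.44, -0.31 from the all-gene median, at percentile 1.46. These included Heyl (0.4 against 14.5 RPKM) and the feedback inhibitor Nrarp (1.3 against 5.7 RPKM). Without the expression filter the medians were -0.26 for integrin and adhesion genes and -0.24 for the Notch pathway.

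Of 26 interferon response genes 10 were at least 2-fold lower in ZnF4 and none at least 2-fold higher, with a median of -0.45, -0.31 from the all-gene median, at percentile 0.29. The drop was not shared by all members, since 8 of the 26 were above wild type by less than 2-fold. The guanylate-binding protein gene Gbp2 was listed at 2.6 against 10.4 RPKM, Rtp4 at 2.1 against 8.2 RPKM, Oas3 at 0.6 against 3.1 RPKM and the regulator Irf7 at 1.9 against 6.7 RPKM. At a mean of at least 5 RPKM the interferon median was -1.06. All 19 granulocyte and monocyte markers were lower than in wild type, 6 of them by at least 2-fold, with a median of -0.86, -0.73 from the all-gene median, at percentile 0.01. Retnlg (6.5 against 24.6 RPKM) and lysozyme, Lyz2 (14.6 against 38.3 RPKM), were the lowest of these. The 7 erythroid markers had a median of 0.65, 0.79 from the all-gene median, at percentile 99.94, and the anion exchanger Slc4a1 was at least 2-fold higher (5.7 against 1.5 RPKM). This median is the value of Hbb-b2, whose reads may be shared with Hbb-b1, so the pair may count as a single measurement. Among the other members, Tfrc, Car2 and Hemgn had log2 ratios of 0.09, 0.21 and 0.34, and Alas2 and Slc4a1 of 0.66 and 1.63. Of these, Tfrc and Hemgn were chosen after their values were seen. Of 8 T-cell markers 3 were at least 2-fold lower, with a median of -0.80, -0.67 from the all-gene median. Without the expression filter the medians were 0.42 for the erythroid and -0.26 for the T-cell markers. The 95% interval of the median over the members spanned 0 for the interferon (-1.12 to 0.08), Notch (-1.53 to 0.19), T-cell (-2.30 to 0.37), integrin (-1.08 to 0.02), pre-B receptor (-0.09 to 0.88) and B-lineage factor lists (-0.20 to 0.32).

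The lowest log2 ratio in the ZnF4 mutant was that of Myl10 (NM_001085387), a regulatory light chain of myosin, at 1.5 RPKM in ZnF4 against 101.8 RPKM in wild type. The sodium channel subunit gene Scn4b (0.7 against 26.5 RPKM), Ccdc135 (1 against 31.3 RPKM), Arpp21 (0.9 against 27.8 RPKM), Gimap4 (1 against 28.1 RPKM), the adaptor Lax1 (0.8 against 23.6 RPKM) and Eps8l1 (0.1 against 8.7 RPKM) were also among the 12 lowest, and Camk2b was listed at 0 in ZnF4 as in ZnF1. Among the highest, Sema5a (NM_009154), a semaphorin, was listed at 15.5 RPKM in ZnF4 against 0.1 RPKM in wild type, and Nrp1, a semaphorin and growth factor coreceptor, at 16.3 against 0.4 RPKM. The adaptor Apba1 (16.5 against 0.2 RPKM), Frmpd1 (13.5 against 0.1 RPKM), the GTPase Rhoj (11.5 against 0.1 RPKM), Fam189a1 (14.8 against 0.5 RPKM), the laminin gene Lamb1 (8.4 against 0.1 RPKM), the sterol hydroxylase Cyp27a1 (24 against 1.5 RPKM), Tgfb2 (6.5 against 0.1 RPKM) and Rassf4 (68.9 against 5.9 RPKM) were higher. The microRNA genes Mir1903 (81 nt) and Mir675 (85 nt) were listed at 20.3 and 5.6 RPKM in ZnF4 and at 0 in wild type.

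**Figure D1:**
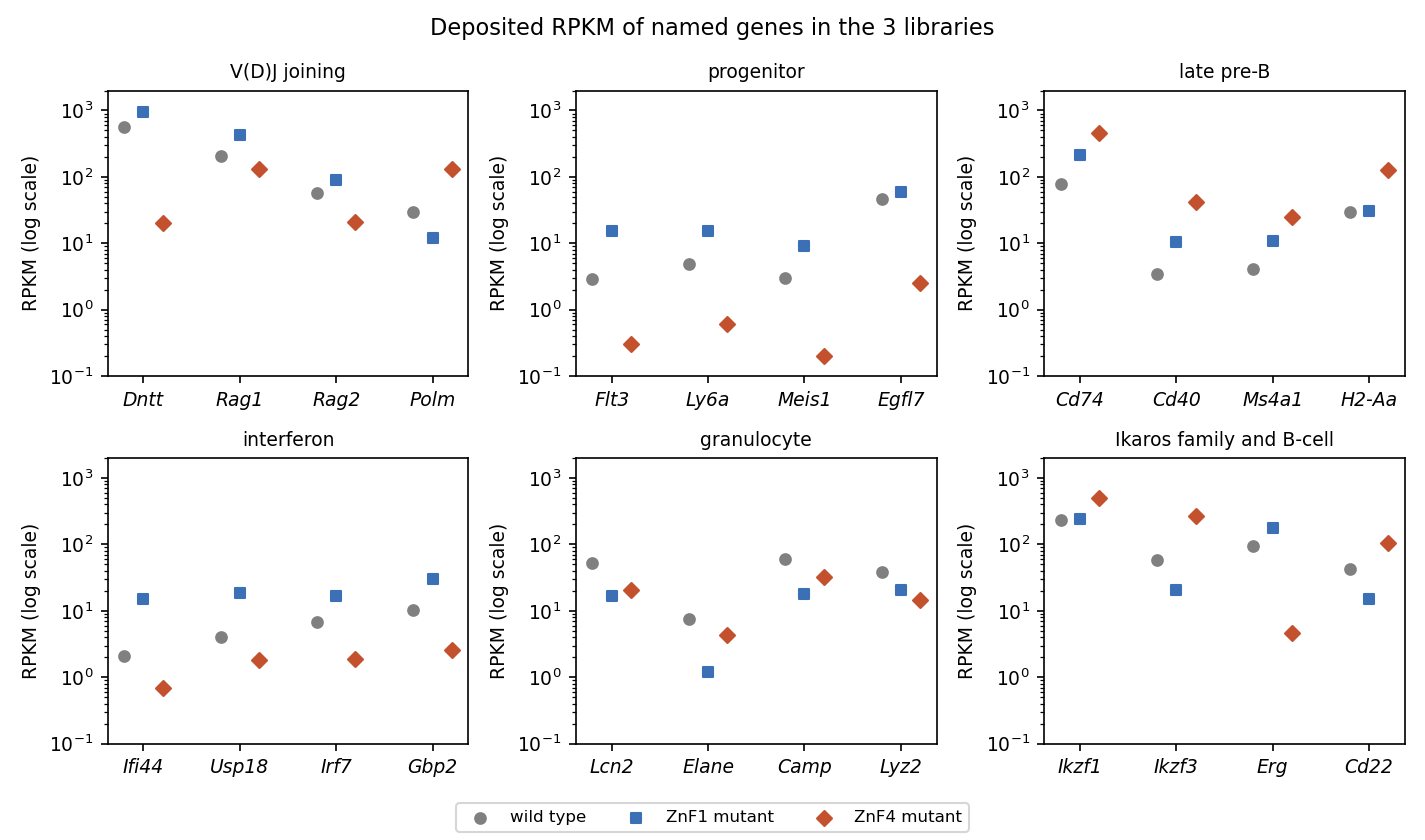
RPKM as deposited, on a log axis, for 24 named genes in the wild-type (circles), ZnF1 mutant (squares) and ZnF4 mutant (diamonds) libraries, 1 library each. Dntt lies at 562.7, 948.8 and 20 RPKM in that order, and Cd74 at 78.5, 212.4 and 462.4 RPKM.

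By the 2-fold rule, more genes differed between the mutants than between either mutant and wild type, with most progenitor and interferon genes lower, and several late pre-B markers and Aiolos higher, in ZnF4 than in ZnF1. There were 582 genes at least 2-fold higher and 800 at least 2-fold lower in ZnF4, 1382 in all, compared with 417 for ZnF1 and 1124 for ZnF4 against wild type. By a 1.5-fold rule the order turned, with 2894 genes between the mutants and 2900 between ZnF4 and wild type. Of the 1382 genes 42.1% were higher, against 49.5% after median-of-ratios scaling, 53.8% after scaling to the same sum and 53.0% after scaling to the same sum without the 20 most abundant genes. The ZnF4 library was at least 2-fold higher than both others for 302 genes and lower than both for 491, and the ZnF1 library was higher than both others for 135 genes and lower for 127.

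Progenitor markers had a median log2 ratio of -2.49 between ZnF4 and ZnF1, with 7 of 11 at least 2-fold lower and 1 higher; the median was -4.45 with a pseudocount of 0.1 RPKM, -0.93 at a mean of at least 5 RPKM and -0.43 without the expression filter. It is the value of Hoxa7, listed at 2.3 RPKM in ZnF1 and at 0 in ZnF4, so the pseudocount sets it, and over the 9 markers listed above 0 in all libraries it was -1.43. Interferon response genes had a median of -1.40, or -2.12 at a mean of at least 5 RPKM, with 18 of 26 at least 2-fold lower. Late pre-B and immature B markers had a median of 0.82, a 95% interval over the members of -0.05 to 1.31, and 10 of 23 at least 2-fold higher and 1 lower. Erythroid markers had a median of 1.83, or 0.66 without the expression filter, with 5 of 7 at least 2-fold higher. The value of 1.83 is that of Hbb-b1, of the near-identical globin pair. Granulocyte and monocyte markers had a median of 0.29. After scaling to the same sum it was 0.50 with the expression filter reapplied, and 0.45 over the same 19 markers. Dntt was listed at 948.8 RPKM in ZnF1 and 20 RPKM in ZnF4, Erg at 175.8 and 4.7 RPKM, Gimap4 at 159.6 and 1 RPKM, and Muc13 at 23 and 0.1 RPKM. The metalloreductase Steap4 (63.6 and 1.7 RPKM), Stat4, a transducer of cytokine signals (42 and 1 RPKM), Fam70a (30.3 and 0.6 RPKM), Gimap3 (21.3 and 0.3 RPKM) and Fxyd6 (98.4 and 3.4 RPKM) were also far lower in ZnF4. In the other direction Hdac9, a histone deacetylase, was listed at 2.1 RPKM in ZnF1 and 41.7 RPKM in ZnF4, Srpk3 at 2 and 52.5 RPKM, Tmprss3 at 0.8 and 25.1 RPKM, Prg3 at 0.4 and 16.4 RPKM and Inppl1 at 1.2 and 25.5 RPKM. Mtap2 was listed at 0 in ZnF1 and at 7.8 RPKM in ZnF4.

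**Figure D2:**
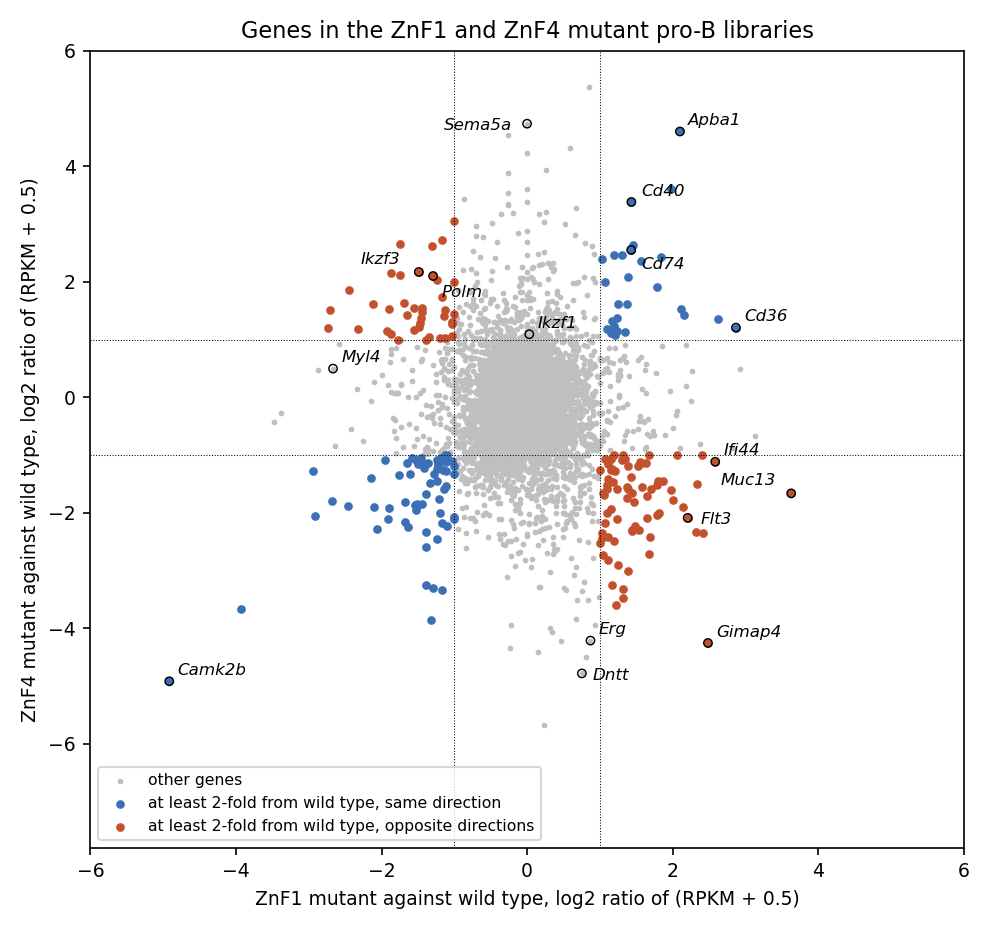
Log2 ratio of (RPKM + 0.5) to wild type in the ZnF1 mutant (horizontal axis) and the ZnF4 mutant (vertical axis) for 10418 genes, 1 point per gene; dotted lines mark 2-fold. Blue points are at least 2-fold from wild type in the same direction in both mutants (27 higher, 64 lower) and orange points in opposite directions (74 and 39).

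Genes apart from wild type in both mutants included Cd74 and Cd40 on the higher side and Lcn2 and Myc on the lower side. Together 27 genes were at least 2-fold higher in both, among them Cd74, Cd40, Ms4a1, Apba1, Cyp27a1 and Cd36, and 64 were at least 2-fold lower in both, among them Camk2b, Slc15a2, Mt1, Lat, Myc, Lcn2 and the immediate early gene Fos (31.6 RPKM in wild type, 8.1 RPKM in ZnF1 and 8 RPKM in ZnF4). Independent lists of these sizes would share 7.10 genes on the higher and 15.99 on the lower side. Unchanged libraries sharing the wild type shared 71.5 (range 51 to 99) and 72.5 (range 50 to 89) in the simulations, so part or all of the agreement could come from the shared wild-type library, which could not be split.

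By the 2-fold rule, more genes lay in opposite directions than in the same direction in the mutants (113 against 91). This turned round without the expression filter (115 against 127) and by a 4-fold rule (4 against 5). There were 74 genes at least 2-fold higher in ZnF1 and at least 2-fold lower in ZnF4 than in wild type, among them Gimap4, Flt3, Ly6a, Meis1, Sell, Cdkn1a, Stat4, Irf7 and Muc13, and 39 genes in the reverse direction, among them Ikzf3, Polm, Cd22, Hdac9 and Inppl1. Independent lists would hold 13.5 and 8.40 such genes, and the simulated unchanged libraries held 1.12 and 1.19 (at most 4 and 5). Across genes, which are not independent replicates, the log2 ratios of the mutants had a Pearson correlation of 0.02, against 0.50 in the simulations, a Spearman correlation of 0.13, and a covariance of 0.007465, against 0.0983 in the simulations. The simulated correlation and the few opposite genes follow from equal noise in the simulated libraries. The real ZnF4 ratios were wider (standard deviation 0.69, against 0.44 for ZnF1), so the simulations give no measure of chance for opposite directions.

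**Figure D3:**
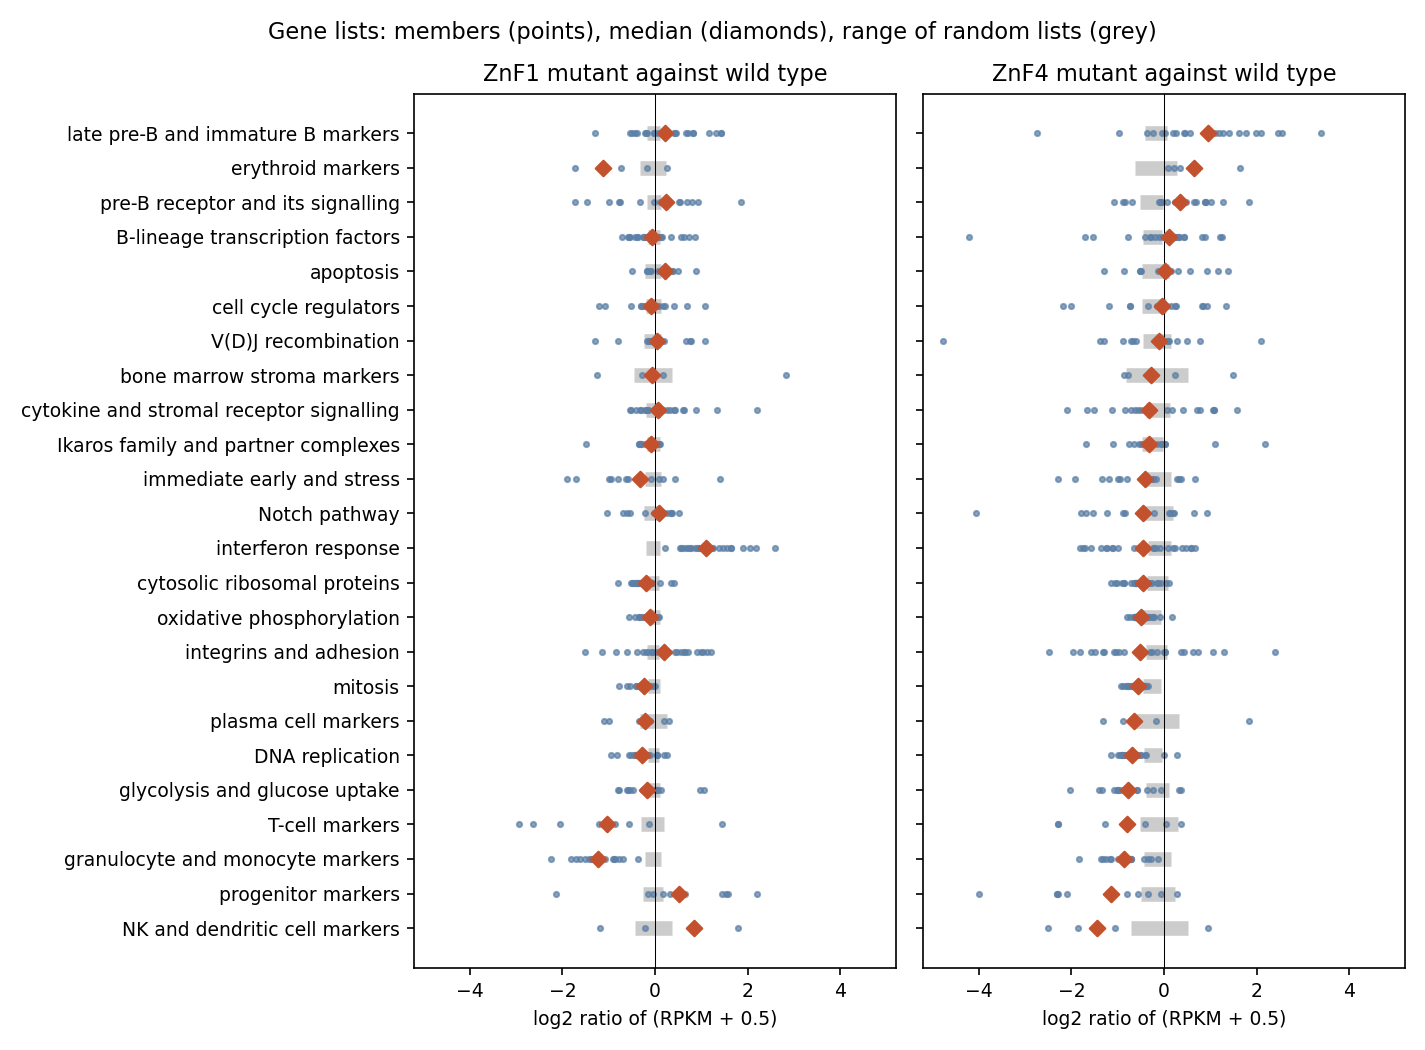
Log2 ratio of (RPKM + 0.5) to wild type for the measured members (points) of 24 gene lists in the ZnF1 mutant (left) and the ZnF4 mutant (right), with list medians as diamonds and the central 95% of random list medians in grey. The interferon list has medians of 1.10 and -0.45, and the progenitor list of 0.52 and -1.14.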

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

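The results flagged in the next paragraph stood out because the mutants lay on opposite sides of wild type, for gene lists beyond the central 95% of random lists in each mutant. Late pre-B markers (medians 0.21 in ZnF1 and 0.95 in ZnF4) and granulocyte markers (-1.22 and -0.86) lay on the same side in both. They are taken up here beside the flagged lists. With 1 library per genotype the difference between the mutants was not tested. The tests of mature B cells, of the mix of stages, of all non-B cells together, of random lists beside the neutrophil genes, of plasmacytoid dendritic cells and of interferon exposure were chosen after the values they rest on had been seen.

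By the 2-fold rule 74 genes were higher in ZnF1 and lower in ZnF4 than in wild type, and 39 were lower in ZnF1 and higher in ZnF4. The median log2 ratio of ZnF4 to ZnF1 was -2.49 for progenitor markers, -1.40 for interferon response genes and 1.83 for erythroid markers. The progenitor value is that of Hoxa7, listed at 0 in ZnF4, and was -1.43 over the markers listed above 0 in all libraries. The erythroid value is that of Hbb-b1, of the near-identical globin pair. Without the expression filter the progenitor median was -0.43 and the erythroid median 0.66, and at a mean of at least 5 RPKM the interferon median was -2.12. It was -0.52 for integrin and adhesion genes, and -2.77 for the 5 measured NK and dendritic cell markers, a median set by Bst2 (45.3 RPKM in wild type, 85.5 RPKM in ZnF1, 12.1 RPKM in ZnF4); without the expression filter this last median was -0.24. The 95% interval of the median over the members spanned 0 for the integrin list (-1.13 to 0.16). The 5 NK and dendritic cell markers are too few for such an interval, and their log2 ratios ranged from -3.35 to 1.17.

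In the ZnF4 library, 6 of 11 progenitor markers were at least 2-fold lower and 11 of 23 late pre-B and immature B markers at least 2-fold higher than in wild type, with 1 late marker at least 2-fold lower. Mature B cells that slipped into the ZnF4 sort would bring Cr2 and Fcer2a, yet neither exceeded 0.3 RPKM in ZnF4. The late markers at least 2-fold higher had a median rise of 20.9 RPKM, and the IgM negative gate excludes most mature B cells. This test covers mature B cells only and leaves late pre-B and immature B cells in the sort untested. The ZnF4 ratios also followed transcript length, with medians from -0.33 in the decile of the shortest genes to 0.09 in that of the longest, but after subtraction of this trend the gap between the list medians was 1.91, against 2.09 before (1.54 and 1.74 without the markers listed at 0). A different mix of the sorted stages, from an altered pace of development, and altered expression within a stage cannot be told apart. The shares of fractions B, C and C′, and of any later IgM negative pre-B cells, within each sort are unknown. Only 2 genes with at least 5 RPKM in ZnF4, both short microRNA genes, were listed at 0 in wild type, and 9 were at 0.1 RPKM or lower there. If the mix of stages were the cause, these few would have to come from a stage that is scarce in the wild-type sort. Altered expression within a stage would not require such a stage.

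All 19 granulocyte and monocyte markers were lower than in wild type in both mutants (13 by at least 2-fold in ZnF1, 6 in ZnF4), while of 7 erythroid markers 6 were lower in ZnF1 (4 by at least 2-fold) and 7 higher in ZnF4 (1 by at least 2-fold). A single change in the share of all non-B cells would move these lists together, but in ZnF4 the erythroid median lay 1.51 above the granulocyte median on the log2 scale, against a summed median absolute deviation of 0.59. That erythroid median is the value of Hbb-b2, of the near-identical globin pair with uncertain levels. Fewer granulocytes and monocytes in the mutant sorts may account for the granulocyte part, since 83.3% of the 12 measured genes of a second neutrophil list (not Trem1 and Padi4) were lower in both mutants, against a mean of 32.1% in random lists matched on expression. The most abundant markers of the main list, S100a9 (291.4, 128.9 and 153.8 RPKM in wild type, ZnF1 and ZnF4) and S100a8 (182.3, 85.8 and 111.8 RPKM), both chosen after their values were seen, are products of cells that a CD19 positive gate should remove. Because both comparisons share the wild-type library, more granulocytes in that single sort would also place the granulocyte markers lower in both mutants. That alone would leave the mutants alike, whereas 15 of 19 markers were higher in ZnF4 than in ZnF1, with a median log2 ratio of 0.29. With 1 library each, this difference was not tested. Why the erythroid markers moved apart also remains open, and myeloid transcripts made by the pro-B cells themselves were not tested.

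Interferon response genes were higher in ZnF1 and, for 10 of 26, at least 2-fold lower in ZnF4 than in wild type. Plasmacytoid dendritic cells, which a CD19 positive gate should remove, express many of these genes, but among Siglech, Ccr9, Cd209d and Pacsin1 the largest difference between ZnF1 and wild type was 0.7 RPKM, against a median rise of 7.4 RPKM for the interferon genes at least 2-fold higher, and Siglech was listed at 0.7 RPKM in wild type and 1 RPKM in ZnF1. These markers were all at 1 RPKM or lower in both libraries, and they leave out Bst2 of the fixed NK and dendritic cell list. Bst2 was listed at 45.3 RPKM in wild type, 85.5 RPKM in ZnF1 and 12.1 RPKM in ZnF4. It moved as the interferon median did in both mutants, so its rise cannot tell such cells from the interferon pattern itself. In the NK and dendritic cell list 3 of 5 members were higher in ZnF1 and 2 lower, with a median of 0.84, or 0 without the expression filter. The low markers alone therefore do not exclude such cells. In ZnF1, 100% of the 26 measured interferon response genes were higher than in wild type, which both the genotype and an interferon exposure of the animals behind this library would give. The genotype and such an exposure cannot be told apart with 1 library per genotype.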

How the results depend on the processing

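The removal of short transcripts, the subtraction of the length trend and the removal of genes listed at 0 in a library were chosen after seeing the data. No list median outside the central 95% of random lists, and no named gene at least 2-fold apart, changed sign under the alternatives run for it, though the median of NK and dendritic cell markers in ZnF1 was 0 without the expression filter. The medians of ZnF4 against wild type ranged from -2.81 to -0.35 for progenitor markers and from 0.76 to 1.11 for late pre-B and immature B markers, and those of the interferon response from 0.92 to 1.23 in ZnF1 and from -1.06 to -0.32 in ZnF4. List medians inside that central range did change sign for the pre-B receptor, V(D)J recombination, cell cycle regulator, cytokine receptor, plasma cell and stroma lists. No paired analysis was possible because each genotype had 1 library. Under the pseudocount of 1 RPKM, the 3 scalings, the sum of a symbol's rows, no expression filter, and the removal of transcripts under 200 nt or of genes listed at 0, all 14 counts of genes stayed within 1.5 times the values reported. The 3 scalings raise the ZnF4 to wild-type ratios by 0.13 to 0.16 on the log2 scale, so the genes at least 2-fold lower are those that scaling can remove; 538 of 737 passed under all 3 scalings as well. For ZnF1 these were 187 of 191 higher and 198 of 226 lower genes. Of 3924 log2 ratios of named genes recomputed, 89 fell below 2-fold and 68 rose above it.

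Fewer genes enter at a mean of at least 5 RPKM, which left 99 genes higher and 109 lower for ZnF1 against wild type, 215 and 451 for ZnF4 against wild type, and 326 and 496 for ZnF4 against ZnF1. With this filter 17 genes were higher and 23 lower in both mutants, and 44 were higher in ZnF1 and lower in ZnF4. ZnF1 stood apart from both others for 67 higher and 70 lower genes, ZnF4 for 172 and 298. A 1.5-fold rule, wider by construction, gave 560 and 700 for ZnF1, 920 and 1980 for ZnF4, and 1222 and 1672 for ZnF4 against ZnF1. By that rule 106 genes were higher and 281 lower in both mutants, 243 were higher in ZnF1 and lower in ZnF4, and 146 the reverse; ZnF1 stood apart for 409 and 334 genes, ZnF4 for 733 and 1196. A 4-fold rule gave 28 and 26 for ZnF1, 87 and 158 for ZnF4, and 152 and 254 for ZnF4 against ZnF1. By the 4-fold rule 1 gene was higher and 4 lower in both mutants, 4 were higher in ZnF1 and lower in ZnF4 and 0 the reverse; ZnF1 stood apart for 20 and 14 genes, ZnF4 for 63 and 124. Genes in opposite directions were fewer than genes in the same direction by the 4-fold rule (4 against 5) and without the expression filter (115 against 127), and more numerous under each other alternative.

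A pseudocount of 0.1 RPKM, which widens the ratios of low genes by construction, gave 47 genes higher in both mutants, 69 lower in ZnF1 and higher in ZnF4, and progenitor medians of -2.81 for ZnF4 against wild type and -4.45 against ZnF1. Scaling, with the expression filter reapplied, moved the ZnF4 to wild-type medians of DNA replication and granulocyte markers towards 0, by construction, to -0.55 and -0.68 with the median of ratios, -0.52 and -0.65 with the same sum, and -0.53 and -0.65 without the 20 most abundant genes; over the same 19 granulocyte markers the scaled medians were -0.72, -0.69 and -0.70. After subtraction of the length trend they were -0.51 and -0.69, and 42 genes were lower in both mutants; the cause was not tested. The correlation of the mutants' log2 ratios, 0.02, was 0.07 without the expression filter and -0.01 at a mean of at least 5 RPKM. Rounding to 0.1 RPKM and the unknown depth limit the genes near 1 RPKM.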

Other observations

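In this part the subtraction of the length trend was chosen after the data had been seen. Several gene lists described less fully above also separated the libraries. Among cytokine and stromal receptor genes, which include Flt3, the feedback inhibitor Socs2 was listed at 20.6 RPKM in ZnF1 against 7.9 RPKM in wild type. In ZnF4 the kinase Jak3 (6.4 against 21.4 RPKM) and Cish (2.5 against 8 RPKM) were lower and the survival kinase Pim2 was higher (21.7 against 7 RPKM). The list medians were 0.06 in ZnF1 and -0.32 in ZnF4, or -0.02 in ZnF1 at a mean of at least 5 RPKM and -0.16 in ZnF4 after scaling to the same sum. Among apoptosis genes, with medians of 0.22 and 0.02, Bcl2l11 was listed at 20.6 RPKM in ZnF1 against 10.9 RPKM, and in ZnF4 Bmf (63.5 against 27.9 RPKM) and Pmaip1 (3.9 against 1.2 RPKM) were higher and Bid was lower (9.2 against 23.4 RPKM). Immediate early and stress genes had medians of -0.32 in ZnF1 and -0.40 in ZnF4, the latter from -0.64 to -0.25 over the alternatives, with Ier2 at 23.4 RPKM in wild type, 11.9 RPKM in ZnF1 and 4.4 RPKM in ZnF4, and Jun at 45.7, 30.4 and 17.8 RPKM.

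In ZnF1, integrin and adhesion genes had a median log2 ratio of 0.20, with Sell at 147.4 RPKM against 63.9 RPKM in wild type and Itga5 at 2.6 against 8.4 RPKM. The Notch pathway had a median of 0.09 and a mean of -0.05, and the glycolysis list -0.18. Ribosomal protein genes had medians of -0.19 in ZnF1 and -0.46 in ZnF4, and oxidative phosphorylation genes -0.10 and -0.49, with no oxidative phosphorylation gene 2-fold apart in either mutant. These are mostly short transcripts, and with the length trend subtracted, the ZnF1 medians were -0.08 and -0.02 and the ZnF4 medians -0.20 and -0.25. NK and dendritic cell markers had medians of 0.84 and -1.44 over 5 members, with Klrd1 at 6.1 RPKM in ZnF1, 1.4 RPKM in wild type and 0.2 RPKM in ZnF4; without the expression filter these medians were 0 and -0.26. Plasma cell markers had medians of -0.22 and -0.64 over 6 members, and bone marrow stroma markers -0.06 and -0.28 over 4; without the expression filter the ZnF1 medians were 0.04 and 0.09 and the ZnF4 medians -0.37 and 0.25. The cell cycle regulator list had medians of -0.08 and -0.05, and the value for ZnF4 turned positive under each of the 3 other scalings, and both did (0.01 and 0.12) with the length trend subtracted. The Ikaros family and partner list had medians of -0.09 and -0.33, the latter from -0.34 to -0.13 over the alternatives. No megakaryocyte marker reached a mean of 1 RPKM. Of the chromosome 11 neighbours of Ikzf1, Fignl1 was listed at 56.8 RPKM in wild type, 33.7 RPKM in ZnF1 and 26.7 RPKM in ZnF4, and Ddc at 8, 6 and 6.4 RPKM.

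Ribosomal protein genes were listed at very different levels, from Rps5 at a mean of 1178.9 RPKM over the libraries to Rps29 at 0.3 RPKM, both chosen after their values were seen; the related gene Rpl10l was listed at 0. A hypothesis was that reads shared with pseudogene copies were not counted. Its test was set before the result was seen and compared each gene's mean RPKM with the percent of its 40-mers that occur in annotated processed pseudogenes. Over 81 genes Spearman's rho was -0.39 and Pearson's r with log2(RPKM + 0.5) was -0.42; the two-sided permutation p for rho was 0.0004 with 10000 permutations, across genes that are not independent replicates. The 27 genes with 50% or more of shared 40-mers had a median of 2.23 RPKM, against 7.58 RPKM for the other 54. This is consistent with the loss of shared reads and leaves much of the spread unaccounted for.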
